A study of Mus musculus with 6 samples.

How the data were processed

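Mature microRNAs were measured in mouse embryoid bodies, the aggregates in which embryonic stem cells begin to differentiate, collected on day 7. Per the labels, the stem cells carried human BRCA1 in its wild-type form (WT), with the missense change M1652I (MI) or with R1699Q (RQ), and each group held 2 biological replicates, so 6 arrays in all. The labels do not state whether the replicates came from separate cultures, and p-values then measure only the spread between these samples, which may be technical. Feeder cells had been removed on gelatin before aggregation, per the labels' protocols. Total RNA was labelled at its 3′ end with T4 RNA ligase, per the labels' protocols, and hybridised to custom Agilent arrays designed from an early release of the miRBase database. Each array had 2 colours. Per the labels, Cy3 carried the group's own RNA and Cy5 the RNA of wild-type embryoid bodies on all 6 arrays, with no dye swap. The files show 1 slide and 1 scan, with both WT arrays in one row of the slide and the MI and RQ arrays in the other.

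The deposited scanner files came from Agilent Feature Extraction 9.5.1.1, per the file headers. They give for each spot the mean intensity and the median local background intensity of either dye on a linear scale, per the file headers. They also give processed intensity values, which the scanner software had corrected for background and normalised between the dyes, per the file headers; which of its dye normalization methods was used is not given in the sources used here. The deposited log10 ratio of each spot is that of processed Cy5 over processed Cy3, per the file headers, and differed from the value recomputed from those intensities by at most 0.0779. The deposited value table of the series held 1932 features. It equalled minus the scanner log10 ratio of each feature, with a largest difference of 0, so its scale and direction (Cy3 over Cy5) are settled and the median of each of its 6 columns was 0. Each deposited file listed 1932 features where its own statistics block counted 14712, and the others were not analysed here.

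Of the listed features, 1336 were spots of 334 mouse microRNA probes, with 4 spots per probe; the 60-base probes carry the microRNA's complement on a shared stem. Names are those of the array's design. Through a table of GRCm38.p6 genes, 290 probe names matched 1 gene symbol, 3 matched several and 41 matched none; no coordinates were used. Control spots (459 positive, 77 negative, and 60 spots of 15 further control probes) were left out of all tests.

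Spot intensities were background-corrected with normexp (offset 50) and normalised by loess within each array, with control spots given no weight, in limma 3.58.1 under R 4.3.3. Spots that the scanner had marked as outliers were removed, between 60 and 99 per array, and the remaining spots of a probe were averaged as log2 Cy3 over Cy5. A probe was tested where over 0.5 of its spots were well above background in either channel on at least 2 arrays, which 294 probes met. Of these, 262 met it in Cy3 and 275 in Cy5. The number of arrays limits the precision. Group means were compared on all 6 arrays with limma's lmFit and eBayes (3 residual and 2.99 prior degrees of freedom), p-values were adjusted by Benjamini-Hochberg over the 294 probes, and a microRNA was called at an adjusted p under 0.05. Where a probe was not well above background in Cy3 on every array of a group, a bound on the fold change of the Cy3 signal was computed after loess and Aquantile normalization. Such a bound is open to dye bias and can exceed the fitted change, which also holds Cy5 and depends on the offset.

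Before the data were examined, 20 lists were fixed: the miR-290, miR-302/367, miR-17-92, Dlk1-Dio3, Sfmbt2, Hox and miR-23/24/27 clusters, the let-7, miR-15/16, miR-30 and miR-181 families, p53-linked and NF-kB responsive microRNAs, and markers of muscle and heart, neural, endoderm, blood, endothelial, epithelial and mesenchymal cells. Lists with at least 3 tested members were tested with camera at its preset correlation, also at an estimated correlation and with fry, and adjusted over the 19 lists tested. With an estimated correlation camera has only the 3 residual degrees of freedom and so little power. Endothelial markers had 1 tested member. The named microRNAs followed a rule fixed at the same time: miR-155 in every comparison, the 12 largest called rises and the 12 largest called falls of each comparison, and up to 4 tested members with the largest absolute change of each list with a call or with a member already named. Any other name was chosen after its values were seen: let-7b, let-7c, miR-152, miR-670, miR-695 and the control probes, the called microRNAs named for holding under every scaling or for opposite signs in the mutants, and the brightest probes of each channel.

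The fit was tested on simulated arrays for RQ minus WT, with 60 of 294 microRNAs changed, over 20 draws. The 60 were drawn from the 248 tested probes well above background in Cy3 on both WT arrays, and no spots were removed as outliers. The shares called thus do not cover probes dim in WT, such as miR-155. With equal Cy3 gain in the groups, 77% of the simulated 2-fold changes and 99.8% of the 4-fold changes were called, 9.78% of calls were unchanged microRNAs, and 2-fold rises had a mean median of 0.80 on the log2 scale. With a Cy3 gain 1.3 times higher in RQ, unchanged microRNAs made up 17.9% of calls under loess and 18.5% under median centring. With no microRNA changed and the Cy3 gain of 1.3 in RQ, the most calls in a draw was 4. The list test was tried on a single draw with independent errors for each microRNA. There the let-7 family, moved as a whole, was called and 0 of the 18 others were. That draw holds no correlation between members, estimated at 0.512 for let-7 in the data, so it does not test the preset correlation.

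Alternatives fixed in advance covered background correction (none, normexp offset 16, the scanner's processed signals), normalization (median centring, loess on bright probes, Aquantile, Cy3 alone), the filter, the averaging of spots, the spread model, the value table, the replicate number as a block, and each array left out in turn. Of these, median centring, loess on bright probes, Cy3 alone and the processed signals are called the 4 other scalings. A filter on Cy3 alone, removal of saturated probes, removal of probes brighter in both channels of the RQ arrays and retention of outlier spots were added after seeing the data.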

Results

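The series asked which microRNAs differ between mouse embryoid bodies with human wild-type BRCA1 and those with a missense change in its C-terminal BRCT repeats, M1652I or R1699Q. The 6 arrays gave a signal well above background for 241 to 255 of 334 mouse microRNA probes in Cy3, the channel of each group's own RNA. The Cy5 reference channel gave 262 to 271. The RQ arrays had a higher net Cy3 signal on negative control spots, with means of 93.05 and 102.8 against 43.79 to 59.44 on the other 4. Replicates correlated at r = 0.987 in WT, 0.993 in MI and 0.994 in RQ across microRNAs, which are not independent replicates of one another. The variance between replicate arrays was, in the median, 2.56 to 4.73 times what the spots of a probe give.

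Stem-cell microRNAs were bright in Cy3 on the WT arrays and most were not well above background in Cy5, although the labels name wild-type embryoid bodies for both channels of the WT arrays. Over the 7 tested members of the miR-290 cluster, the leading microRNA cluster of mouse embryonic stem cells, the median log2 ratio of Cy3 over Cy5 on the WT arrays was 7.60, and 2 of the 7 were well above background in Cy5. The 4 members of the miR-302 and miR-367 cluster had a median of 4.67, and 0 were above background in Cy5. In contrast, the let-7 family had a median of -4.42 and blood markers one of -3.36. The brightest Cy5 probe was miR-451, an erythroid microRNA, at a net signal of 65229, which is saturated on all 6 arrays, followed among others by let-7f (13682), miR-1 (7153), miR-122a (6297) and miR-124a (6236). The ranks of Cy3 and Cy5 signals on a WT array correlated at 0.408 and 0.383, against 0.927 or higher between any 2 arrays in Cy3 and 0.953 or higher in Cy5. The ranks of Cy5 signals were thus close between arrays, although single probes differed on the RQ arrays as given below. Changes are given between groups, and no ratio is read as a level against wild type.

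**Figure D1:**
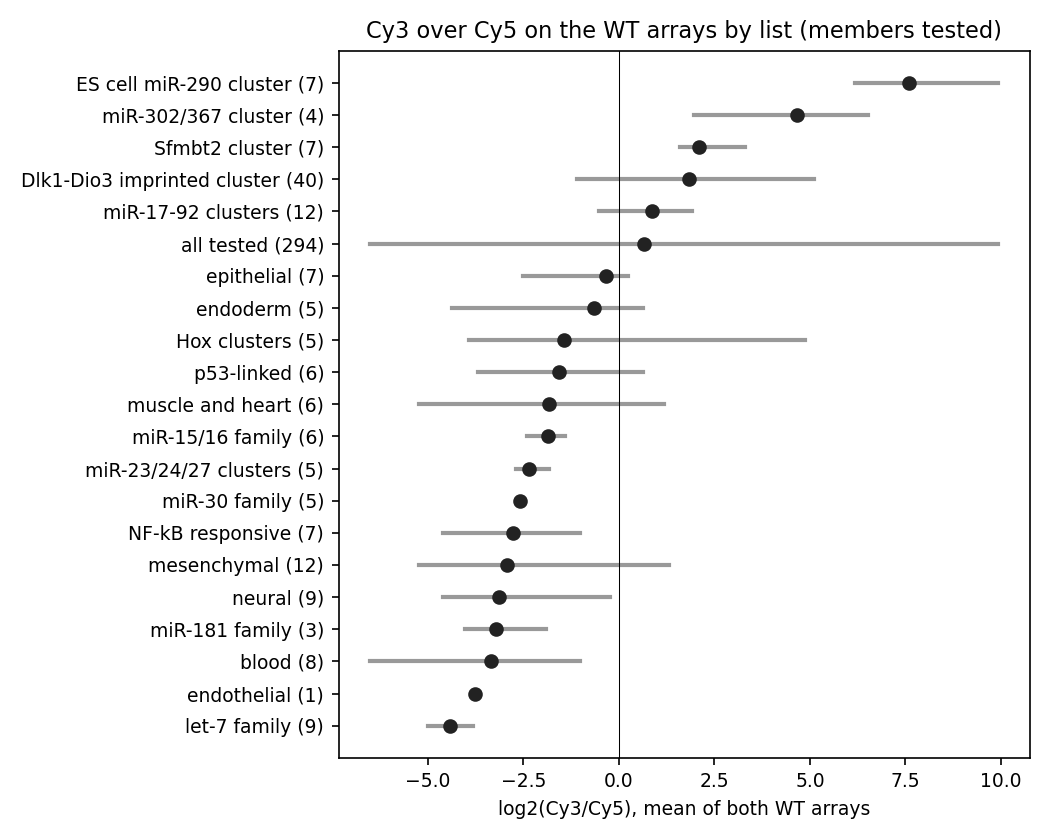
Log2 ratio of Cy3 over Cy5, averaged over both WT arrays, for each fixed list; points are medians over the tested members (their number in brackets) and lines run from the lowest to the highest member. Medians run from -4.42 for let-7 to 7.60 for the miR-290 cluster, against 0.65 over all 294 tested microRNAs.

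In RQ embryoid bodies, miR-652, miR-449, miR-155 and miR-151 rose most against WT, of which miR-652 and miR-155 were also brighter in the reference channel as given below, and miR-200a, miR-26a and miR-27b were among those that fell most. The change was 1.71 ± 0.29 (log2, SE, n = 2 arrays per group) for miR-652, 1.37 ± 0.19 for miR-449, 1.35 ± 0.15 for miR-155, and 1.00 ± 0.13 for miR-151, which lies inside Ptk2. miR-200a, an epithelial microRNA, fell by 1.44 ± 0.18, miR-26a by 1.41 ± 0.14 (not called with median centring, adjusted p = 0.127), and miR-27b by 1.42 ± 0.17. miR-294 of the miR-290 cluster fell by 1.51 ± 0.20 with loess, but was at -0.37 with median centring (adjusted p = 0.193) and -0.24 with Cy3 alone (adjusted p = 0.238), not called in either. Its mean net Cy3 signal was 25517 in WT and 26243 in RQ, while the median tested microRNA on the RQ arrays was at 1.33 times the other 4 arrays. In all, 63 of 294 microRNAs passed, 22 higher and 41 lower (limma, 110 at an unadjusted p under 0.05). Of these, 6 rises and 11 falls were called under each of the 4 other scalings. They were miR-652, miR-449, miR-155, miR-151, miR-361 and miR-491 among the rises. The falls were miR-200a, miR-27a, miR-27b, miR-365, miR-210, miR-148b, miR-499, miR-466, miR-467*, miR-299 and miR-302d.

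Other rises in RQ with loess were miR-672 at 0.98, miR-7 at 0.94, miR-674 at 0.93, miR-19a at 0.85, miR-801 at 0.78, miR-150 at 0.76 and miR-335 at 0.65, all called with median centring too but not with Cy3 alone or the processed signals. Other falls with loess were miR-103 at -1.40, miR-125b at -1.39, miR-107 at -1.35, miR-21 at -1.35, miR-125a at -1.31, miR-29a at -1.21, miR-16 at -1.17 and miR-295 at -1.16; with median centring none of these was called, and they lay between -0.12 (miR-29a) and -0.51 (miR-295). Probes of miR-103 and miR-107 differ at 1 base and may share signal. The falls lay at bright probes, with a median average log2 intensity of 10.32 against 8.13 for the rises, and the loess change minus the median-centred one correlated with intensity at a Spearman rho of -0.646 across microRNAs. With median centring in place of loess, the share of rises among calls went from 34.9% to 70.1% (47 up and 20 down), and 14 of the 41 falls had a positive change. The share was 40% with loess on bright probes, 36.4% with Cy3 alone and 30.6% with the processed signals, and the last 2 moved the median of all microRNAs by -0.10 and -0.30. Without RQ replicate 1 the calls numbered 5, namely miR-155, miR-652, miR-200a, miR-26a and miR-466, without RQ replicate 2 they numbered 40, and without any other array 47 to 60.

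miR-155, processed from the transcript of Mir155hg and known for its part in immune cells and in cancers, was the single microRNA fixed in advance. Its log2 ratio was -1.08 ± 0.05 in WT, -0.84 ± 0.13 in MI and 0.27 ± 0.24 in RQ (SD, n = 2 arrays). RQ exceeded WT by 1.35 (adjusted p = 0.00808) and MI by 1.11 (adjusted p = 0.0157), and MI minus WT was 0.24 (adjusted p = 0.286). In Cy3 it was well above background on both RQ arrays and on 0 of 2 WT arrays, and its Cy3 signal was 3.26-fold higher in RQ. Here the computed bound (1.704, log2) is just the difference of the group means, 8.03 in RQ and 6.326 in WT, so it is no lower limit. That fold leaves Cy5 out, which was brighter too, and is no measure of the RNA if other labelled material added to the signal. The Cy3 spots of miR-155 read 142 to 908 on RQ replicate 1 and 334 to 828 on RQ replicate 2, against 36 to 96 on the WT arrays. The scanner's outlier marks removed 2 of the 4 spots on RQ replicate 1 and 3 of 4 on RQ replicate 2, and with those spots kept the change was 1.76 (adjusted p = 0.00236).

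The miR-155 probe was also brighter in the reference channel of the RQ arrays. Its net Cy5 signal there was 1.59 times that of the other 4 arrays, while the median tested microRNA was at 0.874 times. The ratio of 1.59 is of spot medians and keeps the spots marked as outliers. Without those spots the net Cy5 signal of miR-155 was 140 and 147 on the RQ arrays, against 98 to 106 on the other 4. In all, 18 probes were over 15% brighter in both channels on both RQ arrays than on each of the other 4 arrays, with a net Cy5 signal over 20, against 1 such probe for WT and 0 for MI. They were 11 microRNAs and 7 of the 75 control probes, which name no mouse microRNA. Of the 75, 59 are positive controls, so signal on them may be intended. Among the control probes, ETG10_13482 was 17.2-fold brighter in Cy3 and 11.2-fold in Cy5, and E1A_r60_3 4.77-fold and 8.03-fold. The microRNAs included miR-652 (7.23-fold and 1.91-fold), miR-361 (4.39-fold and 1.77-fold), miR-302c*, miR-670 and miR-695. Of the 22 rises in RQ minus WT, 5 belong to this set (miR-652, miR-155, miR-361, miR-670 and miR-695), and miR-449, miR-151 and miR-491 do not. Without the set, 51 microRNAs were called in RQ minus WT, 16 higher and 35 lower.

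**Figure D2:**
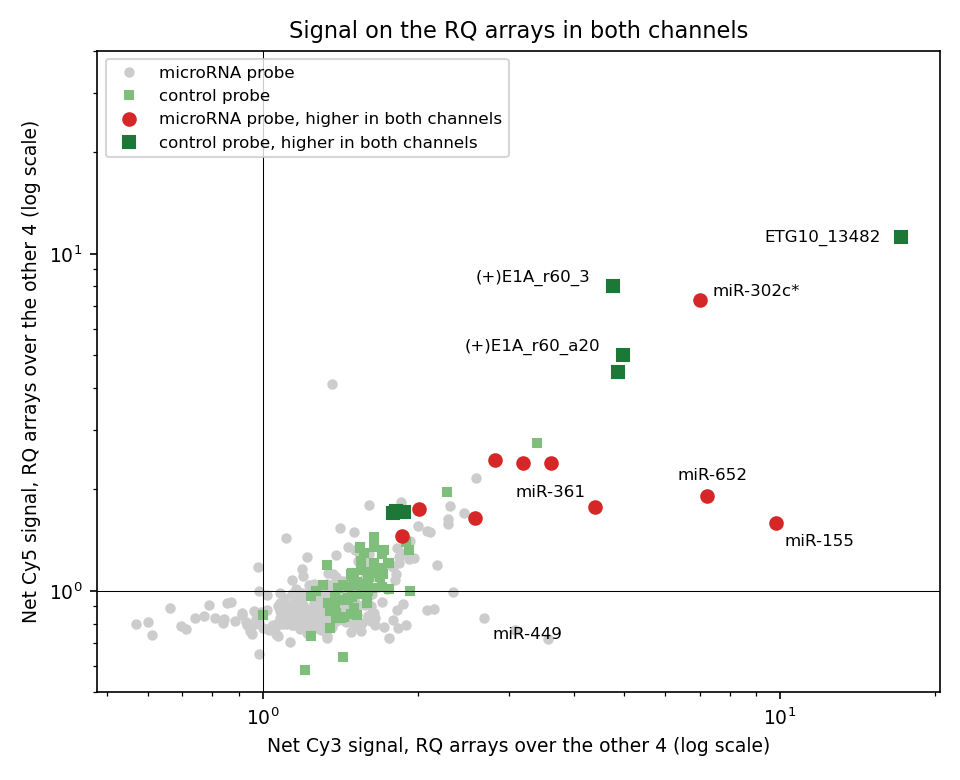
Net signal on the RQ arrays over that on the other 4 arrays, in Cy3 (horizontal) and in Cy5 (vertical), both on log axes, for 293 microRNA probes (circles) and 73 control probes (squares) with a net signal of at least 10; large red circles and dark green squares are the 18 probes that were higher in both channels on both RQ arrays. miR-155, with outlier spots kept, lies at 9.83 in Cy3 and 1.59 in Cy5, and control probe ETG10_13482 at 17.2 and 11.2. Ratios of probes near background on the other 4 arrays are not fold changes of a level.

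The miR-23/24/27 clusters were the 1 list called in RQ minus WT, with all 5 members lower (median change -0.92, camera adjusted p = 0.00125; adjusted p = 0.49 with an estimated correlation). Adjusted over the list alone, 5 of 5 fell. miR-23a changed by -1.06, miR-23b by -0.92, miR-27a by -0.85 and miR-27b by -1.42; the probes of miR-23a and miR-23b, and those of miR-27a and miR-27b, differ at 1 base. The list's adjusted p was 0.382 with median centring, where miR-23a and miR-23b had positive changes of 0.05 and 0.29, 0.284 with Cy3 alone, where miR-23b was at 0.03, and 0.11 with the processed signals.

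Other groups split in RQ minus WT, and the camera adjusted p of each was 0.107 or higher. Of 7 miR-290 members, miR-294 and miR-295 fell and 5 were not called, among them miR-293 at -0.56 and miR-292-5p at 0.28. In the miR-181 family 2 of 3 rose (3 of 3 adjusted over the list alone). Of 7 Sfmbt2 members, repeat-derived microRNAs of an intron of that gene, miR-466 and miR-467* fell by 1.04 and 1.06. In the miR-15/16 family miR-15b fell by 1.16 and miR-16 fell while miR-497 rose by 0.42, though miR-497 was at -0.01 with Cy3 alone, and with median centring miR-15b was near 0 and miR-16 at -0.32, not called. Blood markers split as well: miR-155 and miR-150 rose, and 5 of 8, including miR-146 at 0.42, were not called. miR-451 was called lower, but its ratio has a saturated Cy5 signal and is not read as a change; with Cy3 alone it was not called (adjusted p = 0.212). Of 9 let-7 members 3 fell and 6 were not called, and 3 of 12 mesenchymal markers fell, miR-21, miR-29a and miR-145 (-0.68), with miR-29b at -0.81 not called. Epithelial markers moved both ways, with miR-205 up by 0.61, miR-200a down, and miR-200b (-0.23) and miR-200c (-0.12) among the 5 not called. In the miR-17-92 clusters miR-19a rose and miR-17-5p fell by 0.65, but miR-17-5p was at 0.31 with median centring; miR-19b (-0.67) and miR-106a (-0.47) were not called. Neural markers had 1 rise, miR-153, and 1 fall, miR-125b, with miR-124a (-0.54) and miR-128b (0.39) not called. Of NF-kB responsive microRNAs 1 rose and 2 fell, of muscle and heart markers 2 of 6 fell, and 1 member each fell among the p53-linked, miR-30 and Dlk1-Dio3 lists and the list of the miR-302 and miR-367 cluster. Endoderm and Hox lists had 0 calls among 5 members each.

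miR-153 was not well above background in Cy3 in either RQ or WT and has no fold, and the Cy3 signal of miR-695 was at least 2.11-fold higher in RQ.

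**Figure D3:**
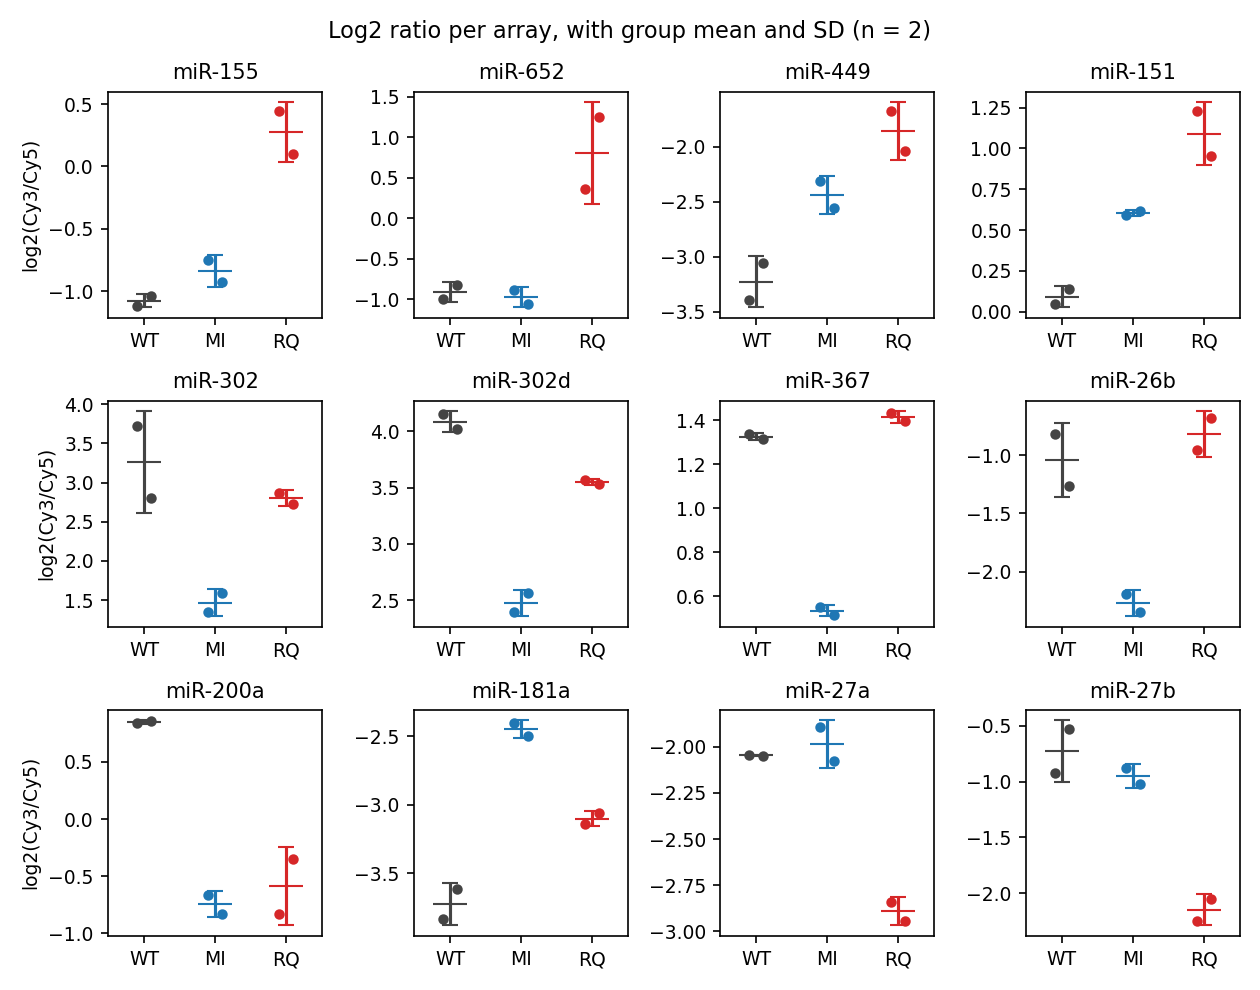
Log2 ratio of Cy3 over Cy5 for 12 named microRNAs in WT, MI and RQ; points are arrays, horizontal bars group means and error bars the SD (n = 2), and each panel has its own vertical scale. The miR-302d mean was lower in MI than in both WT and RQ, and miR-155 was at 0.27 in RQ against -1.08 in WT.

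In MI embryoid bodies the miR-302 and miR-367 cluster, expressed in pluripotent and early differentiating cells and encoded inside Larp7, fell against WT while the miR-181 family rose. miR-302 fell by 1.79 ± 0.29 (log2, SE, n = 2 arrays per group; adjusted p = 0.0132), miR-302d by 1.61 ± 0.12 (adjusted p = 0.0028) and miR-367 by 0.79 ± 0.10 (adjusted p = 0.00604), and miR-302c* was at -0.20 and not called. The cluster's median was -1.20 (camera adjusted p = 0.00218; adjusted p = 0.528 with an estimated correlation), with 3 of 4 lower both over all microRNAs and adjusted over the list alone. All 3 of the miR-181 family rose, miR-181a by 1.28 ± 0.12, miR-181b by 1.06 and miR-181c by 1.00 (camera adjusted p = 0.0115; adjusted p = 0.528 with an estimated correlation). The probes of miR-181a and miR-181c differ at 2 bases. Both lists were called in each of the 4 other scalings, and the miR-181 call was lost without WT replicate 2, when 1 list was called.

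Across all microRNAs 46 of 294 passed in MI minus WT, 27 higher and 19 lower (limma, 108 at an unadjusted p under 0.05). The largest rises were miR-706 at 1.72 ± 0.23, miR-7 at 1.56 ± 0.14, miR-206, a skeletal muscle microRNA, at 1.49 ± 0.33, miR-801 at 1.35, miR-202 at 1.32, miR-491 at 1.28, miR-715 at 1.20, miR-342 at 1.08 and miR-674 at 1.00. miR-200a fell by 1.59 ± 0.18, miR-26a by 1.38 and miR-26b by 1.23. miR-210, induced by hypoxia, fell by 1.11, miR-466 by 0.88, miR-467* by 0.86, miR-15b by 0.82 and miR-130b by 0.81. miR-499, encoded in Myh7b, was not well above background in Cy3 in MI, where its Cy3 signal was 2.37-fold lower. The computed bound (1.243, log2) is close to the difference of the group means, 6.414 in MI and 7.66 in WT. It is thus hardly a lower limit. Under every one of the 4 other scalings 6 rises and 11 falls were called. The rises were miR-7, miR-801, miR-491, miR-181a, miR-181b and miR-181c. In contrast, miR-206, miR-715, miR-674 and miR-15b were each called under 1 of them, and miR-130b under 0.

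The share of rises in MI minus WT was 58.7%, and became 52.5% with loess on bright probes, 44.7% with median centring, 27.3% with Cy3 alone and 28.1% with the processed signals, of which the last 2 moved the median of all microRNAs by -0.11 and -0.16. Leaving out WT replicate 2 raised the 46 calls to 63, and leaving out any other array reduced them, to 6 without MI replicate 1 (miR-181a, miR-200a, miR-26a, miR-302d, miR-491 and miR-7), 19 without MI replicate 2, 28 without WT replicate 1, and 27 without either RQ array, whose spread the fit shares.

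Among the other lists of MI minus WT, with a camera adjusted p of 0.14 or higher, 2 of 7 Sfmbt2 members fell (miR-466 and miR-467*), with miR-669b at -0.18 and miR-297b at 0.09 not called. The miR-15/16 family had 1 rise (miR-497 at 0.53) and 1 fall (miR-15b), with miR-16 at -0.81 and miR-15a at -0.41 not called. Of 7 epithelial markers 1 fell, with miR-205 (0.48), miR-200b (-0.38) and miR-200c (-0.30) not called. Under the 4 other scalings miR-15a, miR-200b and miR-200c were each called lower in 3 and miR-16 in 2, and miR-205 was called in 0. Of 5 miR-23/24/27 members 1 fell. Muscle and heart markers had 1 rise (miR-206) and 1 fall (miR-499), with miR-133b at 0.42 and miR-1 at -0.27 not called. The miR-17-92 clusters had 1 rise and 1 fall, 2 of 12 mesenchymal markers rose, and the Dlk1-Dio3 cluster had 3 rises and 2 falls among 40. The miR-290, let-7, p53-linked, neural, endoderm, blood, Hox, miR-30 and NF-kB lists had 0 members called in limma; 3 of 5 Hox members passed upward when adjusted over the list alone. Blood markers not called included miR-142-5p at 0.44, miR-223 at 0.43 and miR-146 at 0.36, and NF-kB responsive ones miR-21 at -0.58, miR-125b at -0.56 and miR-132 at 0.34. Other scalings called further lists in MI minus WT. The let-7 family was called up with median centring (adjusted p = 0.0209) and Cy3 alone (adjusted p = 0.0353). Epithelial markers were called down with median centring (adjusted p = 0.0209), Cy3 alone (adjusted p = 0.0448) and the processed signals (adjusted p = 0.0351). The Sfmbt2 cluster was called down with median centring (adjusted p = 0.00924) and the processed signals (adjusted p = 0.0351), and by fry (adjusted p = 0.0214), and the Dlk1-Dio3 cluster down with median centring (adjusted p = 0.0228).

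**Figure D4:**
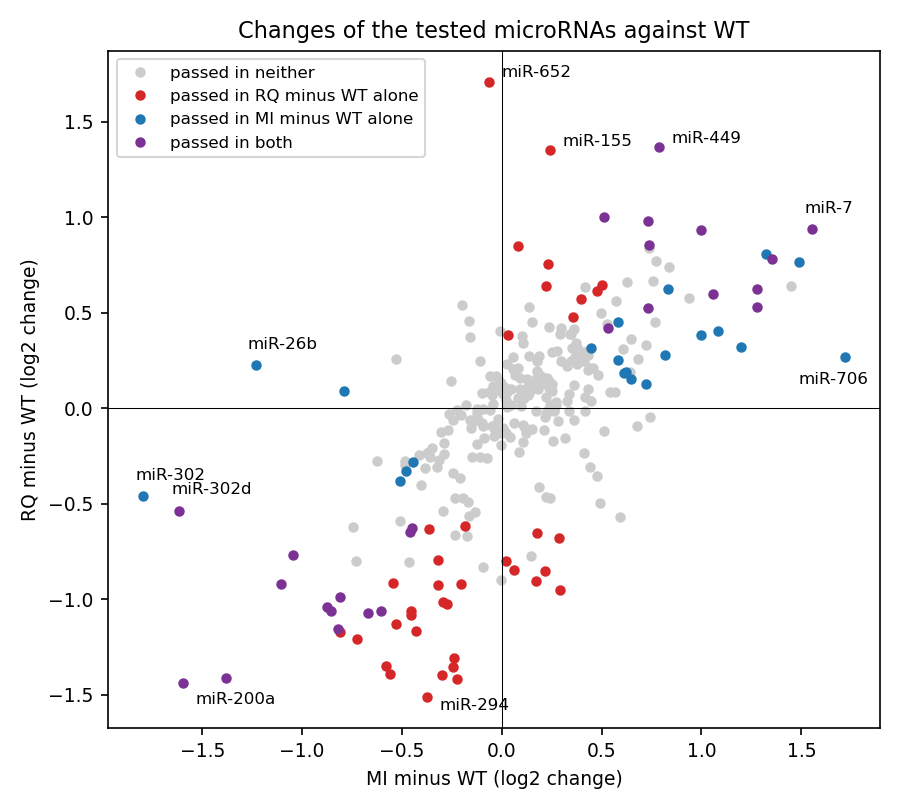
Log2 change of each of the 294 tested microRNAs in RQ minus WT (vertical) against MI minus WT (horizontal), coloured by the comparison in which it passed. 12 microRNAs passed upward in both and 13 downward in both, while miR-155 and miR-652 passed in RQ minus WT alone.

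The changes of both mutants against the shared WT arrays resembled each other. 12 microRNAs were called higher in both, among them miR-491, miR-7, miR-801, miR-181a and miR-181b, and 13 were called lower in both, among them miR-200a, miR-26a, miR-210, miR-466, miR-467*, miR-499 and miR-302d. Independent lists would share 2.02 and 2.65. Unchanged groups simulated against the same WT arrays shared 0 in either direction, but with no change there are few calls to share, so this does not measure the part of the WT arrays. 0 microRNAs were called in opposite directions. The MI calls of miR-449, miR-19a and miR-672, among the 12, held under 0 of the 4 other scalings. The changes correlated at 0.664 across microRNAs, against 0.494 for simulated unchanged groups, and their covariance was 0.179 against 0.0156, a difference of 0.163. They had the same sign for 78.2% of microRNAs, against 66.3%. The 2 WT arrays were not split between the mutants, so part of the excess may come from the shared WT arrays, and both mutants lay in the other row of the slide.

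Set directly against MI, RQ had a higher miR-302 and miR-367 cluster and higher miR-26b, and the probes of miR-652 and miR-155 were higher as well. miR-302 was higher by 1.33 ± 0.29 (log2, SE, n = 2 arrays per group), miR-302d by 1.08 ± 0.12, miR-367 by 0.88 ± 0.10 and miR-302c* by 0.74 ± 0.15. All 4 members were thus called, also when adjusted over the list alone (camera adjusted p = 9.28e-06; adjusted p = 0.455 with an estimated correlation). The list was called in each of the 4 other scalings. The miR-302c* probe, not well above background in Cy3 in MI and at least 3.25-fold higher in Cy3 signal in RQ, is among those brighter in both channels of the RQ arrays, so neither value is read as a change of the microRNA. The cluster was still called without that set. miR-26b was higher by 1.46 ± 0.19. miR-652 was higher by 1.78 ± 0.29 and miR-155 by 1.11 ± 0.15, and as both belong to that set the same limit holds for them. miR-34a, a target of p53, was higher by 0.79 and miR-187 by 0.53, neither of them called with Cy3 alone.

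In the other direction miR-706 was lower in RQ than in MI by a change of -1.45 ± 0.23 (not called with Cy3 alone, adjusted p = 0.218), miR-27b by -1.19 ± 0.17, miR-365 by -1.08 ± 0.13 and miR-27a by -0.91 ± 0.12. The Cy3 signal of miR-152 was 1.91-fold lower. Its computed bound (0.936, log2) is close to the difference of the group means, 6.271 in RQ and 7.222 in MI, so it is hardly a lower limit. Further falls were miR-320 (-1.24), miR-744 (-1.16), miR-294 (-1.14), miR-107 (-1.11), miR-103 (-1.10), let-7g (-1.07), miR-125a (-1.07) and miR-145 (-0.97). Of these, miR-744 was at -0.18 with Cy3 alone (adjusted p = 0.756) and not called with loess on bright probes (adjusted p = 0.0574); its net signal on the RQ arrays was 4.12 times that of the other 4 in Cy5 and 1.36 times in Cy3, so its fall lies largely in the reference channel. miR-294 was at -0.30 with median centring and 0.02 with Cy3 alone, not called in either. The direction of miR-320 turned with median centring (0.08) and Cy3 alone (0.64). miR-107, miR-103, miR-125a and let-7g were at -0.30, -0.30, -0.29 and -0.365 with median centring and not called. In all 32 of 294 passed, 9 higher and 23 lower (limma, 78 at an unadjusted p under 0.05), and 5 rises and 7 falls were called under each of the 4 other scalings. The share of rises was 28.1%, and 37.5% with loess on bright probes, 61.3% with median centring, 45.5% with Cy3 alone and 40.7% with the processed signals. Median centring moved the median of all microRNAs by 0.16. Leaving out MI replicate 1, MI replicate 2 or RQ replicate 2 left 0 calls in limma (60, 47 and 58 at an unadjusted p under 0.05), and leaving out RQ replicate 1 left 1 (53 unadjusted), while leaving out either WT array gave 48.

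The miR-23/24/27 clusters were lower in RQ than in MI with 2 of 5 members called and 5 of 5 adjusted over the list alone (camera adjusted p = 0.0157; adjusted p = 0.455 with an estimated correlation). miR-23a was at -0.46 and miR-24 at -0.43. The miR-181 family was lower with 2 of 3 called, miR-181a at -0.65 and miR-181c at -0.61, and miR-181b at -0.46 not called (camera adjusted p = 0.0454; adjusted p = 0.57 with an estimated correlation). Mesenchymal markers, which feeder fibroblasts also hold, were lower with 2 of 12 called, miR-145 and miR-214 (-0.59), and miR-21 at -0.77 and miR-29c at -0.63 not called (camera adjusted p = 0.0454; adjusted p = 0.57 with an estimated correlation). These 3 calls were lost with median centring, Cy3 alone and the processed signals, and miR-214 was at 0.15 with median centring and 0.17 with Cy3 alone. Without RQ replicate 1 the call of the miR-302 and miR-367 cluster was the 1 left, and without MI replicate 1 it and the miR-23/24/27 call were the 2 left. The mesenchymal and miR-181 calls were also lost without the probes brighter in both channels.

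The other lists of RQ minus MI had a camera adjusted p of 0.0563 or higher. Among 7 miR-290 members miR-294 fell and 6 were not called, including miR-295 (-0.73), miR-290 (-0.64) and miR-291a-5p (-0.43), and this list was called down without either WT array or RQ replicate 2, with no background correction, with no filter, with outlier spots kept, and with the arrays of RQ and MI alone. The miR-17-92 clusters were called up with median centring. 1 of 9 let-7 members fell, with let-7d at -0.90, let-7a at -0.72 and let-7f at -0.72 not called. 1 of 6 p53-linked members rose, miR-34a, with miR-34b at -0.32 and miR-34c at -0.27 not called. miR-155 was the 1 blood marker and the 1 NF-kB responsive microRNA called. miR-150, at 0.52, was not called in the main limma fit (adjusted p = 0.067) but was called higher under each of the 4 other scalings. The miR-17-92, muscle and heart, neural, endoderm, epithelial, Dlk1-Dio3, Sfmbt2, Hox, miR-15/16 and miR-30 lists had 0 members called in limma.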

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

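All tests of explanations in this part were chosen after the results they bear on had been seen.

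10 microRNAs were called in RQ minus MI, called against WT in one mutant, and had changes of opposite sign against WT in the mutants. let-7g was at -1.07 (RQ minus MI, log2; adjusted p = 0.037), miR-145 at -0.97, miR-148b at -0.82, miR-27a at -0.91, miR-320 at -1.24, miR-365 at -1.08 and miR-500 at -0.83, each of which fell in RQ and had a positive change in MI that was not called. miR-26b was at 1.46 and miR-367 at 0.88, and both fell in MI. miR-652 was at 1.78, called in RQ alone, and its probe was brighter in both channels of the RQ arrays. The sign of miR-320 turned with median centring (0.077) and with Cy3 alone (0.64), and the RQ minus MI calls of miR-320 and miR-500 each held under 1 of the 4 other scalings. The positive sign in MI held under 0 of them for miR-148b and 1 each for miR-27a and miR-365, so for these the opposite signs are not firm. Nor was the opposing change called for any of the 10. It was as small as -0.065 in MI for miR-652 and 0.091 in RQ for miR-367, and was 0.217 in MI for let-7g and 0.225 in RQ for miR-26b.

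Added control probes, left out of all comparisons, were mostly brighter in Cy3 in the mutants. All 15 of them had a higher net Cy3 signal on both RQ arrays than on both WT arrays, and 12 did so on both MI arrays. In RQ this is not particular to control probes, as the median tested microRNA was at 1.33 times the other 4 arrays in net Cy3 signal. The U6 3p22_rc probe, for a spliceosomal RNA, read 13444 in RQ and 10398 in MI against 7397 in WT in Cy3, while in Cy5 it read 5806, 6188 and 7433. The AgilentLinker probe read 6198 on RQ replicate 2, owing to 1 spot of 24044, with a median of 254. Among 18 probes brighter in both channels on both RQ arrays, control probe ETG10_13482 read 844 in Cy3 against 49 on the other 4 arrays, E1A_r60_a20 read 514 against 104, and DCP_20_0 read 514 against 106.

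On the WT arrays Cy3 and Cy5 held different microRNAs, although both are labelled wild type. The 11 members of the miR-290 cluster and the miR-302 and miR-367 cluster lay 9.55 log2 units (SD 2.39) above the 28 members of the blood, muscle, neural and endoderm lists in Cy3 over Cy5, more than a dye bias between labellings of the same RNA would give across probes of one design. Of those 11, 2 were well above background in Cy5 against 10 in Cy3, as RNA of other tissues in the reference would give. A candidate explanation is thus that Cy5 carried RNA of differentiated tissues, such as a pooled reference, and no biological explanation was tested. The labels and the arrays disagree here, and the comparisons against WT rest on the WT arrays.

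miR-155 was higher in RQ than in WT and MI, and the row of the slide is argued against by the difference of 1.11 from MI in the same row. A higher Cy3 background and labelling of the RQ arrays stays open, since miR-155 was not well above background in WT: among 93 probes as dim there, 1 (miR-302c*) had as large a ratio of RQ over WT, but ratios at that level exclude nothing. Extra labelled material on the RQ arrays stays open too. There 7 of 75 control probes, which name no mouse microRNA, were brighter in both channels. So was miR-155, by 1.59-fold in Cy5 with outlier spots kept. As 59 of the 75 control probes are positive controls, their rise alone does not show stray material. For miR-155 the Cy5 increase was 0.115 of the Cy3 increase, the lowest of the 18 probes. The 7 control probes ran from 0.171 (DCP_22_2) to 0.333 (ETG10_13482). The value of 0.115 may be too low. Its baseline is the Cy5 signal of the other arrays, and the median tested microRNA in RQ was at 0.874 times theirs. Across the miR-155 spots Cy5 also followed Cy3. On RQ replicate 1 it went from 242 at a Cy3 of 908 to 91 at 142. On RQ replicate 2 it went from 215 at 828 to 147 at 334. Spots of 1 probe can vary in both channels together whatever RNA they bind, so this does not tell such material from miR-155. Extra labelled material could account for part of the signal, and for all of it is not ruled out. An effect of R1699Q on miR-155 also stays open and was not separated from it.

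The miR-302 and miR-367 cluster was lower in MI than in WT and RQ. Fewer undifferentiated cells would also lower the miR-290 members, whose median in MI minus WT was 0.34 (SD 0.39, n = 7) against -1.20 for the cluster, and -0.12 against -1.27 with Cy3 alone. These values do not bear on a loss of early differentiating cells, which also express the cluster, and that was not tested. The row of the slide is argued against by a median of 0.98 in RQ minus MI, from arrays of the same row, and normalization by the list's adjusted p of at most 0.00591 under the 4 other scalings. A candidate explanation is an effect of M1652I, or of a difference between the cell lines carrying it, on this cluster; it was found and tested on the same 2 arrays per group.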

How the results depend on the processing

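Alternatives concerning the Cy3 filter, saturated probes, probes brighter in both channels and outlier spots were chosen after seeing the data; the others were planned. miR-155 in RQ minus WT stayed higher and called, from 1.18 without RQ replicate 1 (adjusted p = 0.0466) to 3.73 with the processed signals, except against 0 without the WT arrays (0.27, adjusted p = 0.0591), and it was not tested without the probes brighter in both channels, being one of them. Testing against 0 called 269 microRNAs in RQ and 260 in MI, and 14 lists in each, which by construction reads the unlike reference channel; it was run for no other single microRNA. The call of the miR-302 and miR-367 cluster kept its direction in MI minus WT and in RQ minus MI under all settings of the list test but the estimated correlation, and apart from tests against 0. With an estimated correlation 0, 0 and 0 lists were called in RQ minus WT, MI minus WT and RQ minus MI. That setting leaves camera the 3 residual degrees of freedom, so its lost calls do not show that list members were correlated. For the miR-23/24/27 clusters the estimated correlation was -0.088, yet their camera adjusted p in RQ minus WT went from 0.00125 to 0.49. It was 0.449 for the miR-302 and miR-367 cluster and 0.455 for the miR-181 family. Correlation within these 2 lists is thus not set aside, and their p-values at the preset correlation may be too small. The fry test called 3 lists in RQ minus WT, adding the Sfmbt2 cluster and the miR-181 family. For the same 3 comparisons in that order, the processed signals called 0, 4 and 1 lists, the series matrix 0, 4 and 1, median centring 0, 6 and 2, and Cy3 alone 0, 4 and 1. In RQ minus MI lists numbered 1 with a normexp offset of 16, and 2 with the filter on all 6 arrays, the median of spots, the filter on Cy3 alone, and without probes brighter in both channels. MicroRNA calls numbered 7 in RQ minus MI with no background correction and 14 with outlier spots kept, and 27 in MI minus WT when only those 2 groups were fitted. Median centring turned miR-17-5p (0.31), miR-23a (0.047) and miR-23b (0.29) of RQ minus WT and miR-320 (0.077) and miR-214 (0.15) of RQ minus MI to positive changes. Cy3 alone turned miR-497 (-0.007) and miR-23b (0.027) of RQ minus WT and miR-320 (0.64), miR-294 (0.019) and miR-214 (0.17) of RQ minus MI. Apart from fewer arrays or probes and the reference channel, the cause was not tested. Leaving out an array gave 5 (without RQ replicate 1) to 60 calls in RQ minus WT, 6 (without MI replicate 1) to 63 in MI minus WT and 0 (without MI replicate 1, MI replicate 2 or RQ replicate 2; 60, 47 and 58 at an unadjusted p under 0.05) to 48 in RQ minus MI; a lone array was assumed to vary like the other groups. miR-155 ranged from 1.18 to 1.52, and lists numbered 1 in RQ minus WT, 1 to 2 in MI minus WT and 1 to 4 in RQ minus MI. The replicate block gave 59, 39 and 38 microRNAs, 1, 2 and 3 lists, and 1.35 for miR-155; replicates with a shared number correlated in their deviations at 0.182, 0.119 and 0.041 over 2 pairs, so the numbers were not taken to pair the arrays. Aquantile leaves ratios unchanged by construction. A slide block was not run with 1 slide, nor probes of all species, since all 334 probes name a mouse microRNA. Fitted changes of probes not well above background in a group depend on the background setting (miR-155 was at 1.92 with a normexp offset of 16) and are not sizes of a change in level.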

Other observations

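let-7b and let-7c, chosen after their values were seen, were brighter in Cy3 on the RQ arrays. Their mean net Cy3 signals were 1963 and 1809 in RQ, 753 and 528 in MI, and 527 and 499 in WT. In the loess fit their changes in RQ minus WT were 0.17 and 0.25 and were not called (adjusted p = 0.739 and 0.546). With median centring they were 1.99 and 2.03, with Cy3 alone 1.39 and 1.38, and with the processed signals 1.20 and 1.29, each called. The probes of let-7b and let-7c differ at 1 base. In the same comparison let-7a, let-7f and let-7g fell in the loess fit, by 1.02, 0.92 and 0.85. Their mean net Cy3 signals were 397, 435 and 226 in WT and 479, 400 and 237 in RQ. The median tested microRNA on the RQ arrays was at 1.33 times the other 4 arrays in Cy3. The median change of the let-7 family was 0.17 with loess and 0.29 with median centring.

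miR-26a and miR-26b, whose probes differ by 4 base changes, shifts counted, parted between the mutants. miR-26a fell by 1.41 in RQ (not called with median centring) and 1.38 in MI against WT, while miR-26b fell by 1.23 in MI and was at 0.23 in RQ, and the RQ minus MI difference of miR-26b was 1.46 (adjusted p = 0.0146). miR-451 was saturated in Cy5 on all 6 arrays. miR-690 and miR-709 read 65241 in Cy3 on the WT arrays, at the scanner's limit, so a rise in them could not be measured.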
